A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

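RNA-seq of budding yeast was compared between WT and tSH2Δ cells, with 3 libraries each. Per the labels' protocols, cells from a saturated culture were set to an OD of 0.2 in YPD, a rich glucose medium, and harvested after 4 h. RNA was extracted with acid phenol and treated with DNase, rRNA was depleted with a stranded total RNA kit, and single-end reads of 50 bases were sequenced. The 6 ATAC-seq libraries of the series were not analysed here.

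The authors deposited RPKM values of 6571 genes in each library, that is reads per kilobase of gene length, scaled to the total reads of the library. Per the submitters' processing notes the genome build was sacCer3, and the tools named for the RNA-seq and ATAC-seq data together were Bowtie 1.1.2, Bowtie2, SAMtools 0.1.9 and 1.3.1, bedtools 2.25.0, HTSeq 0.6.1, Trim Galore 0.4.1, deepTools 2.2.4, DESeq and DESeq2, with no role for each. The gene annotation, the strand setting of the counting and the handling of reads that match several places are not given in the sources used here. A stranded kit counted without strand would give a gene and its antisense partner each other's reads. The open reading frame YKL153W, which lies opposite GPM1, was listed at 6223 and 1804 RPKM in WT and tSH2Δ, and GPM1 at 6275 and 1864, so values of overlapping genes are uncertain. The authors also deposited a table of 2890 genes with mean RPKM, a log2 ratio and an adjusted p-value. Per the file headers, the log2 ratio is that of the mean RPKM values plus 1, and the adjusted p-value is from the authors' DESeq2 test. The genes listed in the authors' deposited table all have an adjusted p-value of 0.0495 or less and a log2 ratio of 0.5 or more in size.

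RPKM times gene length was a whole multiple of a single step in each library for 100% of values (tolerance 0.01 reads), which gave the reads per gene and the library totals. The totals were 20483931 to 27069700 reads, with 84.6% to 87.6% in genes. A row that names no gene held 0.513% to 0.926% of the reads and was left out. Replicate pairs were compared by a chi-square test of these reads over genes. Chi-square per gene lay between 3.12 and 18.5, so no pair agreed within sampling noise. Each library was counted as a sample, though this spread does not tell separate cultures from separate preparations of the same culture.

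The unit is RPKM, so the test was limma (lmFit, then eBayes with an intensity trend, version 3.58.1 in R 4.3.3) on log2(RPKM + 1). This scale understates the change of low genes. Before this, libraries were scaled by median-ratio size factors of the RPKM, which were 0.811 to 0.828 in WT and 1.20 to 1.23 in tSH2Δ. These scaled values are called rescaled RPKM. Genes with at least 1 RPKM in at least 3 of the 6 libraries were tested, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. There was no block for replicate number, since the labels do not say that a number marks a shared culture or day.

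Before the data were examined, 30 gene lists were fixed from general knowledge of yeast. None was chosen on these samples. The 3 lists of mitochondrial genome, snoRNA and Ty genes had 0 members in the table, and the other 27 were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over lists. Each list was also set against 10000 random lists of the same size matched on mean level in 40 bins. Shares of summed RPKM were compared by an exact two-sided permutation test, which with 3 against 3 libraries cannot give a p under 0.1.

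The rule for named genes was fixed at the same time. It takes SPT6, the 10 genes with the largest rises and the 10 with the largest falls among called genes with a standard name, groups that do not overlap and a mean of at least 5 rescaled RPKM in the higher group. For each list described it takes up to 2 called members with the largest rise and up to 2 with the largest fall. Genes named outside this rule are said to be chosen after their values were seen or to be neighbours of such a gene. YKL153W, also outside the rule, was named as an example of overlap.

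Gene names and coordinates came from the RefSeq table of assembly R64, the assembly of the sacCer3 build. Of the 6571 gene IDs 5897 matched and 674 did not, and coordinates are 1-based spans of annotated genes.

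The fit was tested on simulated reads for the tSH2Δ against WT comparison, with 6273 genes tested and 50 genes at each fold. It recovered 40% of genes changed 1.2-fold, 92% at 1.5-fold, 94% at 2-fold and 100% at 4-fold. It called 11 of 6075 unchanged genes (0.181%). The simulation changed few genes, evenly up and down, with a dispersion of 0.003 for every gene. In the real data 83.5% of genes were called, so these rates need not hold there.

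Alternatives covered the pseudocount (0.1 and 5 RPKM), the filter (none, and at least 5 RPKM), the scaling (none, quantile normalization of the log2 values, and total-sum scaling without ribosomal protein genes), the variance model, library weights, a replicate block, leaving out each library and a minimum log2 fold change of 1. Added after seeing the data were limma's voom on the whole reads, leaving out chromosome XI, keeping RefSeq genes alone and shares of reads. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.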

Results

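RNA was measured by sequencing in budding yeast (Saccharomyces cerevisiae) that carried either wild-type SPT6 (WT) or an allele without the tSH2 domain (tSH2Δ). The column labels name the background S288C for WT and none for tSH2Δ, so they do not show that the strains differ at SPT6 alone. Spt6 is a histone chaperone that travels with RNA polymerase II, and the tandem SH2 (tSH2) domain near its C terminus binds the polymerase. The comparison asked how mRNA levels differed between the strains, in a study of the part Spt6 plays in mRNA stability. There were 3 libraries per strain, from cultures grown in rich medium for 4 h after dilution, and 6 ATAC-seq libraries of the same strains were not analysed here. The RNA libraries held 20483931 to 27069700 reads, with 17575916 to 23722190 of them in genes. Across genes, log2 values correlated at 0.996 or more between replicates and at 0.915 to 0.918 between strains. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. RNA levels alone do not separate synthesis from decay.

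SPT6 itself (YGR116W, chromosome VII, 720409 to 724764, sacCer3) was lower in tSH2Δ. Its rescaled RPKM was 180.4 ± 5.69 in WT and 84.7 ± 0.790 in tSH2Δ (SD, n = 3), a log2 fold change of -1.08 (SE 0.0353, limma adjusted p = 3.5e-08). With RPKM as deposited the log2 fold change was -0.50. The RPKM is a mean over the whole annotated gene, including the part absent from the mutant allele. All fold changes below are on the log2(RPKM + 1) scale and relative to the median gene, which stood 0.57 higher in tSH2Δ in the RPKM as deposited.

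Among called genes with a standard name and at least 5 rescaled RPKM in the higher group, HSP12 had the largest rise. HSP12 (YFL014W, chromosome VI, 107256 to 107585), a small stress protein, went from 34.2 ± 2.85 to 650.2 ± 372 rescaled RPKM (SD, n = 3), a log2 fold change of 4.06 (SE 0.324, limma adjusted p = 4.67e-06). MPC3, a subunit of the mitochondrial pyruvate carrier, followed at 3.62. SER3 (YER081W, chromosome V, 322686 to 324095), which encodes a dehydrogenase of serine synthesis, rose from 46.9 ± 2.58 to 503.9 ± 2.37, a log2 fold change of 3.40 (SE 0.0435, limma adjusted p = 1.96e-09). NCE103, the carbonic anhydrase, rose by 3.29, the hexokinase gene HXK1 by 3.22 and the glutamate decarboxylase gene GAD1 by 3.02. PCL1, a G1 cyclin of the kinase Pho85, rose by 2.84, RTC3 and the proline permease gene PUT4 each by 2.83 and TMA10 by 2.76. HSP12 and NCE103 differed widely among the tSH2Δ libraries, with 1074 and 2853 rescaled RPKM in replicate 3. Without that library their log2 fold changes were 3.63 and 2.88.

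By the same rule TIR1 had the largest fall. TIR1 (YER011W, chromosome V, 175248 to 176012), a cell wall mannoprotein gene, went from 45.0 ± 2.95 to 2.42 ± 0.211 rescaled RPKM (SD, n = 3), a log2 fold change of -3.75 (SE 0.0739, limma adjusted p = 7.48e-09). FIT2, a mannoprotein gene of siderophore-iron uptake, changed by -3.34, and ANB1, the translation factor gene made at low oxygen, by -3.12. HAP1, which encodes a heme-responsive transcription factor, changed by -2.80, the glucanosyltransferase gene GAS2 by -2.67 and TIR3 by -2.62. The other 4 of these 10 genes lie on chromosome XI. They were FBA1, the glycolytic aldolase, at -2.95, HOT13 at -2.70, YRA2 at -2.67 and TMA19 at -2.58. FBA1 (YKL060C, chromosome XI, 326408 to 327487) went from 15734 ± 2136 to 2024 ± 113 rescaled RPKM (SD, n = 3). The direction of each gene named in this paragraph and the one before was the same under every scaling tried.

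**Figure D1:**
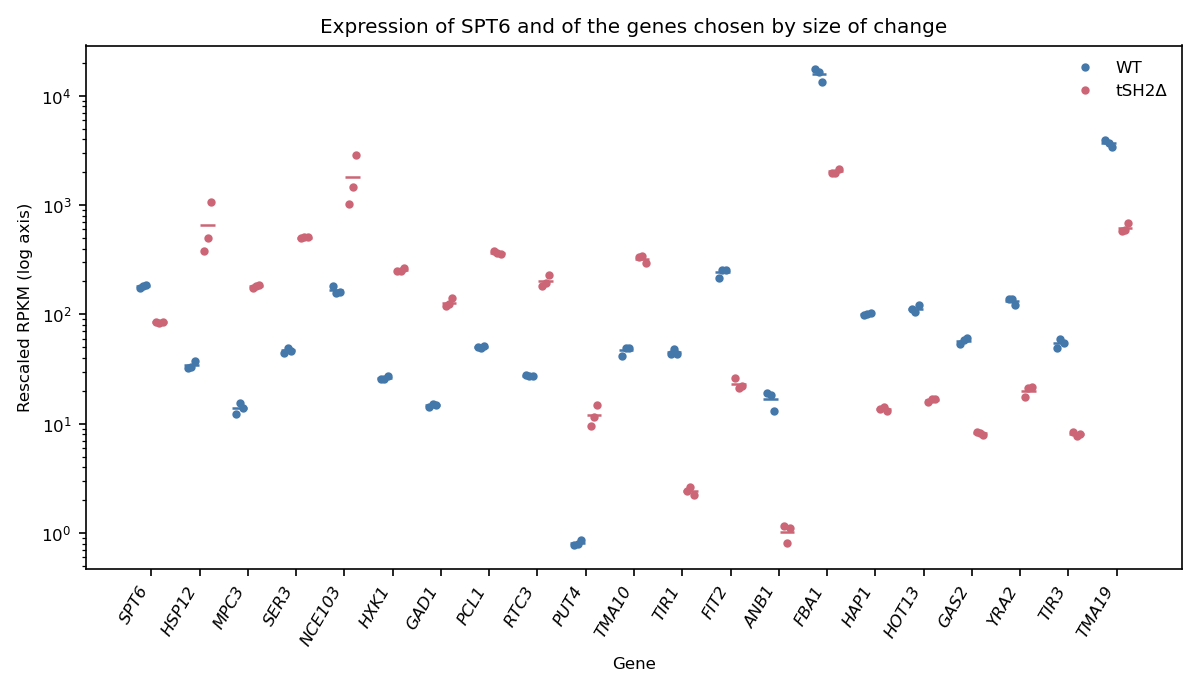
Rescaled RPKM (log axis) of SPT6, of the 10 named genes with the largest rises and of the 10 with the largest falls; each point is a library (3 WT, 3 tSH2Δ) and each bar the group mean. The WT and tSH2Δ points do not overlap for any gene shown, and the widest spread is that of HSP12 and NCE103 in tSH2Δ.

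Of 6307 genes tested, 5267 (83.5%) differed between the strains, 2627 of them higher and 2640 lower in tSH2Δ (limma, Benjamini-Hochberg adjusted p under 0.05). A log2 fold change of at least 1 in size was reached by 498 of the higher and 599 of the lower genes. The values of the groups did not overlap for 5341 genes (84.7%), where chance gives 10%. With RefSeq genes alone, a setting added after seeing the data, 4850 of 5718 genes were called, 2423 higher and 2427 lower. The balance between rises and falls depends on the scaling. After scaling to the median gene 49.9% of the calls were higher, and with RPKM as deposited 80.7% were, with 4565 genes higher and 1091 lower. In the authors' deposited table, 2405 genes were higher and 485 lower. Of those higher in the authors' deposited table, 2380 were also called higher here, 21 were not called and 4 were not tested. All 485 lower genes of the authors' deposited table were called lower. That table lists neither 2155 of the genes called lower here nor 247 of those called higher. Across the 2886 genes in common the log2 fold changes here and in the authors' deposited table correlated at 0.999, and genes are not independent replicates. Both come from the same RPKM values plus 1, apart from the scaling, so this correlation is no independent support. The match of lower genes has the same source, since scaling to the median gene lowers all fold changes nearly alike.

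Genes of ribosome production were lower after scaling to the median gene. Of 138 cytosolic ribosomal protein genes, 132 were lower, 3 higher and 3 not called, with a median log2 fold change of -0.96 (-0.38 with RPKM as deposited). RPL17A (-2.29) and RPL14A (-2.07), both on chromosome XI, fell furthest, while RPL22B (0.98) and RPL35B (0.83) rose. The list stood below other genes in limma's camera test (adjusted p = 9.5e-16), but not with an estimated correlation (adjusted p = 0.733) nor after quantile normalization (adjusted p = 0.168). After quantile normalization 67 of its members were lower and 36 higher, and its median lay at -0.12 relative to all genes. Of 76 ribosome biogenesis factors, which build the ribosome subunits, 74 were lower and 0 higher, with a median of -0.92 (-0.34 as deposited). EBP2 (-2.21) and RPF2 (-2.12), also on chromosome XI, led them (camera adjusted p = 9.5e-16, and adjusted p = 0.48 with an estimated correlation). After quantile normalization 70 of the 76 were lower, with a median of -0.56 relative to all genes (camera adjusted p = 3.64e-11). Without the 5 and 4 members on chromosome XI, 127 of 133 ribosomal protein genes and 70 of 72 biogenesis factors were lower. Many ribosomal protein genes have near-identical copies, and how reads were shared between copies is not given in the sources used here.

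Genes of glycolysis and fermentation were also lower. Of 22 members 16 were lower and 5 higher, with a median log2 fold change of -1.28 (-0.70 as deposited). FBA1 and the phosphoglycerate mutase gene GPM1 (-2.33), both on chromosome XI, fell furthest, GPM1 with reads that its overlap with another open reading frame leaves uncertain, and the glycerol phosphatase gene GPP2 rose by 1.47. The camera adjusted p was 0.00584, and adjusted p = 0.733 with an estimated correlation. After quantile normalization 17 were lower and 3 higher, with a median of -0.40 relative to all genes (camera adjusted p = 0.0226). Among 53 amino acid biosynthesis genes 38 were lower and 11 higher, with a median of -0.57 that turned to 0.01 with RPKM as deposited, where 24 were higher and 19 lower. The glycine cleavage gene GCV3 (-1.51) and the threonine synthase gene THR4 (-1.41) fell, and ARG3 (1.73) and CPA1 (1.48) of arginine synthesis rose. This list's camera adjusted p was 0.00286, with adjusted p = 0.733 with an estimated correlation and adjusted p = 0.284 after quantile normalization. The members on chromosome XI numbered 2 of the glycolysis list and 1 of the amino acid list.

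Chaperone and histone genes were lower after scaling to the median gene. Of 19 heat shock factor targets 17 fell, led by the chaperone genes SSA2 (-1.78) and HSC82 (-1.34), while MBF1 (0.44) and CUR1 (0.38) rose. The median was -0.58, and -0.0038 as deposited, where 6 were higher and 7 lower (camera adjusted p = 0.00194, and adjusted p = 0.526 with an estimated correlation). None of the 19 lies on chromosome XI. Of 11 histone genes 9 fell and 2 were not called, with HTA1 at -0.83 and HTB1 at -0.74, and the median of -0.53 was 0.05 as deposited, where 5 were higher and 2 lower. Their camera adjusted p was 0.0242, with adjusted p = 0.48 with an estimated correlation. This call was also lost with RPKM as deposited (adjusted p = 0.343) and with total-sum scaling (adjusted p = 0.135). After quantile normalization both lists stood on the other side of the rest of the genes, without passing the test (adjusted p = 0.869 and 0.757), and HTA1, no longer called, and HTB1 had log2 fold changes of -0.07 and 0.17. Without the histone gene on chromosome XI, 8 of the other 10 were lower. Both list medians lay above the median of lists matched on level (-0.77 for heat shock factor targets and -0.75 for histones). Neither fall was thus larger than that of genes at the same level.

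Stress and glucose-repressed genes rose. Of 60 environmental stress response genes, a set induced by many stresses, 52 were higher and 4 lower, with a median log2 fold change of 1.05 (1.58 as deposited). HSP12 and HXK1 rose furthest, and the thioredoxin gene TRX2 fell (-0.82). The disaggregase gene HSP104 was lower (-0.45) only after scaling to the median gene, at 0.13 as deposited, 0.03 with total-sum scaling and 0.10 after quantile normalization. The list's camera adjusted p was 3.95e-09, and adjusted p = 0.48 with an estimated correlation. Of 42 galactose and glucose-repressed genes 30 were higher and 3 lower, with a median of 0.60 (1.16 as deposited). The galactose-induced reductase gene GCY1 (2.53) and the maltose permease gene MAL31 (2.41) rose, and the galactose pathway repressor gene GAL80 (-1.40) and the invertase gene SUC2 (-0.93) fell. The camera adjusted p of this list was 0.000209, and adjusted p = 0.48 with an estimated correlation. After quantile normalization 23 were higher and 12 lower (camera adjusted p = 0.0361). The members on chromosome XI numbered 1 of the stress list and 3 of the glucose-repressed list, none of them higher and called. With chromosome XI left out before scaling and fitting, 51 of 59 and 29 of 39 were higher.

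**Figure D2:**
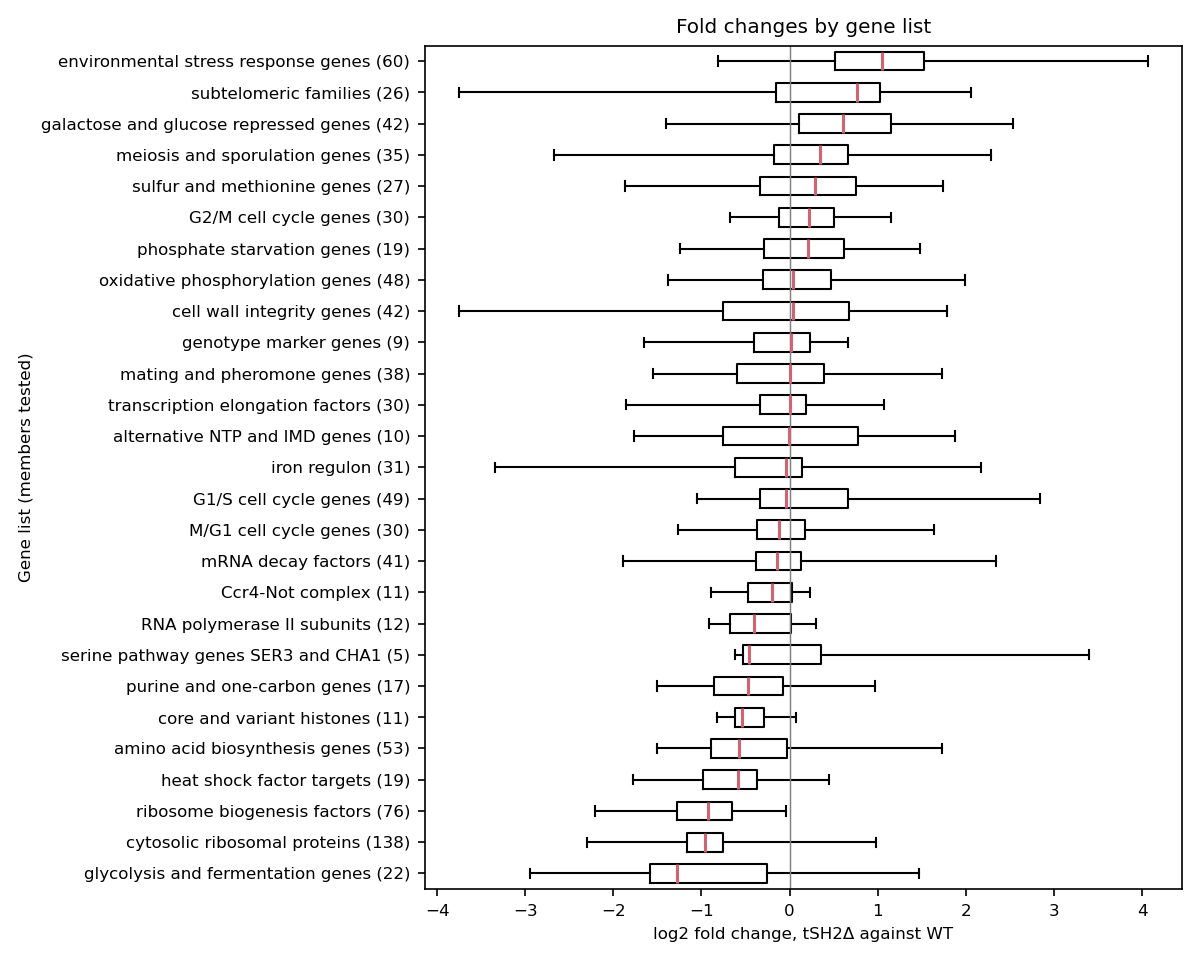
Log2 fold changes of tSH2Δ against WT for the members of the 27 gene lists with at least 5 genes tested, after scaling to the median gene; the box spans the quartiles, the coloured line is the median and the whiskers run to the lowest and highest member. The medians run from -1.28 for glycolysis and fermentation genes to 1.05 for environmental stress response genes.

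None of the lists of mRNA turnover and transcription passed the camera test. Of 11 Ccr4-Not genes, which encode the main mRNA deadenylase complex, 6 were lower and 2 higher (camera adjusted p = 0.3). The deadenylase gene CCR4 changed by -0.89 (limma adjusted p = 9.15e-08) and the scaffold gene CDC39 by -0.85 (limma adjusted p = 8.39e-08), while MOT2 rose by 0.23. Of 41 mRNA decay factors 21 were lower and 11 higher (camera adjusted p = 0.333). The poly(A)-binding protein gene PAB1 fell by 1.89, and the decapping enhancer gene EDC1 rose by 2.34 and DCS1 by 0.87. Of 30 transcription elongation factors 11 were lower and 12 higher (camera adjusted p = 0.956), with ELF1, on chromosome XI, at -1.86, CHD1 at -0.98, BUR2 at 1.07 and DST1 at 0.40. Of 12 RNA polymerase II subunit genes 8 were lower and 2 higher (camera adjusted p = 0.171), with RPO21, the largest subunit, at -0.91 and RPB9 at 0.30. These counts depend on the scaling. With RPKM as deposited 8 Ccr4-Not genes were higher and 2 lower, 34 decay factors higher and 4 lower, 24 elongation factors higher and 2 lower, and 7 polymerase subunit genes higher and 3 lower.

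Cell cycle lists had no camera call, and after scaling to the median gene their members went both ways. Of 49 G1/S genes 22 were higher and 22 lower (adjusted p = 0.783), of 30 G2/M genes 18 and 8 (adjusted p = 0.22), and of 30 M/G1 genes 10 and 16 (adjusted p = 0.523). With RPKM as deposited the counts of higher and lower genes were 39 and 4, 27 and 0, and 23 and 6, in the same order. In the G1/S list the median was -0.04 while the mean, 0.18, and the direction of the test were positive. Among G1/S genes PCL1 and the repressor gene YHP1 (1.40) rose, and the flap endonuclease gene RAD27 (-1.05, chromosome XI) and POL2 (-0.80) fell. Among G2/M genes the kinesin partner gene CIK1 (1.16) and TEM1 (1.05) rose, and SFG1 (-0.67) and the chitin synthase gene CHS2 (-0.61) fell. Among M/G1 genes the cell wall protein gene PIR3 (1.64, chromosome XI) and the cyclin gene PCL2 (1.31) rose, and PIR1 (-1.27, chromosome XI) and the chitinase gene CTS1 (-1.19) fell.

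Of 48 oxidative phosphorylation genes 21 were higher and 17 lower, with a median of 0.04 (camera adjusted p = 0.68). The cytochrome genes CYC1 (2.00) and CYT1 (1.22) rose, and MDH1 (-1.38) and SDH3 (-1.24), both on chromosome XI, fell. MDH1 is a citric acid cycle gene, and the list holds others, such as CIT1 and ACO1. After quantile normalization this list stood above other genes (camera adjusted p = 9.53e-05). An estimated correlation was run only with the median-gene scaling, where it gave adjusted p = 0.918. Of 31 iron regulon genes 14 were lower and 8 higher (adjusted p = 0.815), with FIT2 and the ferroxidase gene FET3 (-1.43) down and the heme oxygenase gene HMX1 (2.17) and ISU1 (1.61) up. Of 42 cell wall integrity genes 19 were higher and 16 lower, 9 of the 42 lying on chromosome XI (adjusted p = 0.985). The glucan synthase gene GSC2 (1.78) and PIR3 rose, and TIR1 and TIR3 fell. In this list the mean, -0.13, had the opposite sign to the median, 0.04. Of 17 purine and one-carbon genes 11 were lower and 2 higher (adjusted p = 0.0581), with ADE6 at -1.17 and IMD2 at 0.97. This list passed the test without WT replicate 3 (adjusted p = 0.0191) and with voom on the whole reads (adjusted p = 0.0495), both at the preset correlation. With all libraries it had adjusted p = 0.774 with an estimated correlation. Of 27 sulfur and methionine genes 17 were higher and 7 lower (adjusted p = 0.227), with MET10 at 1.75 and MET22 at -1.86. In the list of 5 serine pathway genes SER3 and CHA1 (0.36) were higher and the remaining 3 lower (adjusted p = 0.881). Among those 3, SER33 (-0.52) stood at 0.05 with RPKM as deposited. The mean of this list, 0.43, had the opposite sign to its median, -0.46. With RPKM as deposited the counts of higher and lower genes in these lists were 39 and 4 for oxidative phosphorylation, 21 and 6 for iron, 27 and 11 for cell wall integrity, 8 and 5 for purine and one-carbon, 21 and 4 for sulfur and methionine, and 3 and 0 for serine genes.

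For all lists, adjusted over the list alone the counts of higher and lower members equalled those over all genes tested, except in the iron regulon with 7 rather than 8 higher. Of the 27 lists tested, 8 passed camera with the preset correlation (6 down, 2 up). With an estimated correlation 0 of the 27 passed, and 0 had an unadjusted camera p under 0.05, the smallest being 0.0501 for the environmental stress response genes. By limma's fry, which tests whether members change in either direction and does not compare a list with other genes, 27 passed.

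Genes of chromosome XI were lower in tSH2Δ along its whole length. Their median log2 fold change was -0.86 over 313 genes (-0.29 with RPKM as deposited), against medians between -0.0088 and 0.15 on the other 15 chromosomes. On chromosome XI 88.5% of genes were lower, against 34.1% to 43.6% elsewhere. The chromosome held 10.9% ± 0.0941 of the reads in genes in WT and 5.73% ± 0.0465 in tSH2Δ (SD, n = 3, exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). It holds 4.96% of the genes tested and 132 (22.0%) of the 599 genes with a log2 fold change of -1 or less. Of the 485 lower genes in the authors' deposited table, 119 (24.5%) lie on chromosome XI. Without the genes of chromosome XI, a setting added after seeing the data, 4936 genes were called, 2459 higher and 2477 lower.

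**Figure D3:**
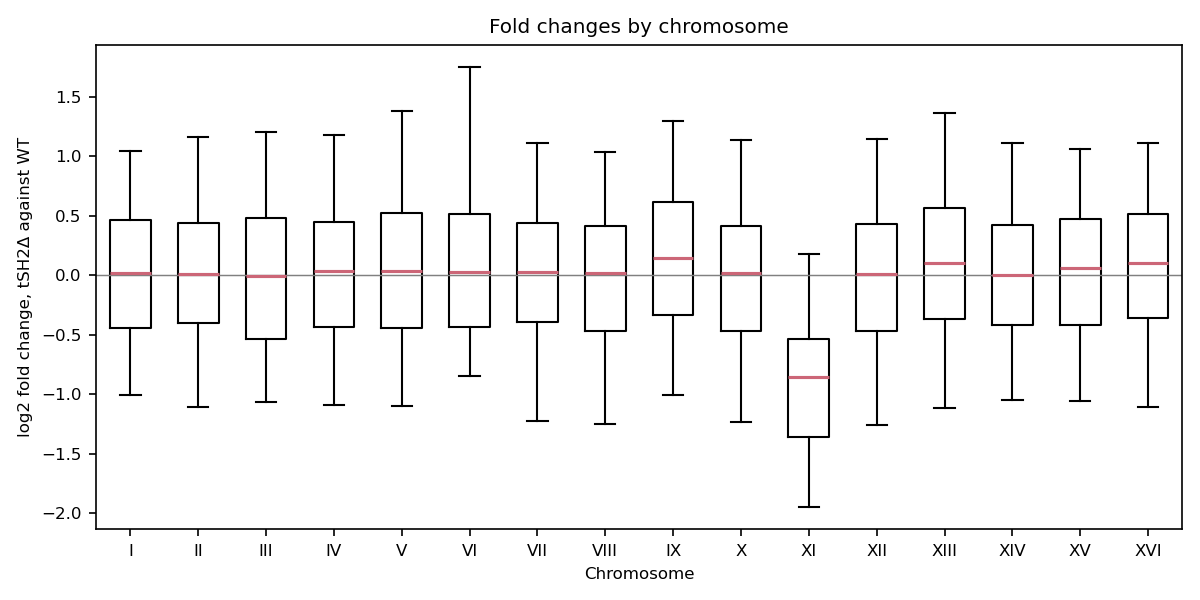
Log2 fold changes of tSH2Δ against WT for tested genes, by chromosome; the box spans the quartiles, the coloured line is the median and the whiskers leave out the lowest 5% and the highest 5% of genes. The median of chromosome XI is -0.86 and those of the other 15 chromosomes lie between -0.0088 and 0.15.

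Transcripts of the most abundant genes took up less of the tSH2Δ libraries. Ribosomal protein genes made up 20.2% ± 0.525 of the summed RPKM in WT and 15.2% ± 0.621 in tSH2Δ (SD, n = 3, exact two-sided permutation p = 0.1, the smallest possible). Glycolysis and fermentation genes went from 6.77% ± 0.479 to 2.76% ± 0.116, and the 10 genes with the highest RPKM in each library from 8.91% ± 0.158 to 5.46% ± 0.0799, with the same exact p = 0.1 for both. The glycolysis share includes FBA1 and GPM1 of chromosome XI, and the other shares can hold genes of that chromosome too. In WT, FBA1 stood at 15734 rescaled RPKM, and GPM1 and the overlapping YKL153W at 6275 and 6223 RPKM. No share without chromosome XI is given here, so its part in these falls was not tested. Across the 6307 genes the log2 fold change fell with mean level (Spearman's rho -0.47), and the median went from 0.37 in the lowest to -0.83 in the highest of 10 equal groups by level. Genes are not independent replicates in this relation.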

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

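The settings added after seeing the data were voom, leaving out chromosome XI, RefSeq genes alone and shares of reads. The edgeR and DESeq2 alternative was not run, because the files hold RPKM, and limma's voom on the whole reads took its place with 5281 genes called. The balance of directions depends on the scaling. Genes higher and lower numbered 4565 and 1091 with RPKM as deposited and 4259 and 1314 with total-sum scaling, which shift the median log2 fold change to 0.57 and 0.47. A minimum log2 fold change of 1 left 1097 genes, 498 higher and 599 lower, by its construction. The difference in ribosomal protein share was -2.59 as a share of reads and -5.01 as a share of RPKM, which divides by gene length. In every other setting the counts stayed within 1.5 times. Leaving out each library in turn gave 4956 to 5183 genes called, 2458 to 2581 higher and 2498 to 2602 lower, 2770 to 2827 shared with the authors' deposited table, SPT6 in tSH2Δ against WT at -1.11 to -1.07 and a library composition difference of -5.37 to -4.83. PUT4 was not tested without a tSH2Δ library, since too few libraries passed the filter.

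Of 2179 values of named genes under alternatives, 2155 kept direction and call, 17 lost the call and 7 changed direction. The latter were HSP104 (0.13), SER33 (0.051) and BAR1 (0.022) as deposited, HSP104 (0.026) with total-sum scaling, and CAF16 (-0.0051), HTB1 (0.17) and HSP104 (0.10) after quantile normalization. With RPKM as deposited and total-sum scaling all genes shift nearly alike relative to the main scaling, by construction. For quantile normalization the cause was not tested. Many named genes were picked for large changes, so these counts do not hold for all genes. Of the 2640 genes called lower, 948 were called higher with RPKM as deposited, 660 with total-sum scaling and 217 after quantile normalization. Of the 2627 called higher, 44 were called lower after quantile normalization and 0 under the other 2 scalings. Of 567 list results 550 kept their call or lack of one, without regard to the direction of lists not called, 12 lost the call and 3 gained it. The other 2, histones (adjusted p = 0.757) and heat shock factor targets (adjusted p = 0.869), lost the call and changed direction after quantile normalization, where the cause was not tested. Lists without a call changed direction too, among them mRNA decay factors (as deposited, total-sum scaling and quantile normalization), RNA polymerase II subunits and meiosis genes (quantile normalization) and cell wall integrity genes (as deposited and others). The 8 camera calls were all lost with an estimated correlation. Leaving out the intensity trend, robust variance and library weights cannot change camera as run here, which took only the values and the design. List results under those settings kept their call by construction and are no evidence of stability.

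With replicate number as a block (replicate block) 5052 genes were called, 2518 higher and 2534 lower. Libraries of the same number had deviations correlated at -0.25, -0.086 and -0.28, which shows no sign of pairing by number. Deviations from a mean of 3 libraries are tied to each other, so these values cannot exclude a shared culture or day. CAF16 lost its call under the block (adjusted p = 0.0787), and no call of another named gene or list changed. At the depth and replicate number of these libraries 40% of simulated 1.2-fold changes were recovered, with a dispersion of 0.003 for every gene. Neither depth nor replicate number was varied.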

Other observations

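Of the tests in this part, those of windows along chromosome XI, of the stress score and of the ribosome lists taken singly were chosen after the values they measure had been seen. So were AAC3, HEM13, ROX1, CYC7, YBR012C, YBR013C and YER053C-A, while the other genes follow the rule for named genes or are neighbours of YBR013C.

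Some further single genes had these values, with no test of them as a group. The ADP/ATP carrier gene AAC3 had a log2 fold change of -2.02 (SE 0.113) and the heme synthesis gene HEM13 of -1.56 (SE 0.0499). The cytochrome c gene CYC1 rose by 2.00 (SE 0.0821), and the hypoxic repressor gene ROX1 by 0.74 (SE 0.0937). The gene of the other cytochrome c form, CYC7, went from 14.6 ± 3.47 to 72.0 ± 2.91 rescaled RPKM (SD, n = 3). Among mating genes 15 of 38 were higher and 18 lower (camera adjusted p = 0.881). The alpha-agglutinin gene SAG1 (1.73) and the karyogamy gene KAR5 (1.48) rose, and the a-factor gene MFA1 (-1.55) and the a-factor exporter gene STE6 (-1.44, chromosome XI) fell. Of 35 meiosis and sporulation genes 18 were higher and 8 lower (adjusted p = 0.3), against 11 and 14 after quantile normalization, with RED1 at 2.29 and IME1 at -1.98. Of 26 subtelomeric family genes tested, out of 76 listed, 16 were higher and 6 lower (adjusted p = 0.141), of 19 phosphate starvation genes 9 and 6 (adjusted p = 0.534), and of 10 genes of nucleotide synthesis 4 and 4 (adjusted p = 0.881). In the subtelomeric list AAD4 stood at 2.06, PAU7 at 1.98, TIR1 at -3.75 and TIR3 at -2.62. That list was made by gene family name, and not all members are subtelomeric. TIR1 (chromosome V, 175248 to 176012) and TIR3 (chromosome IX, 333727 to 334536) lie away from the chromosome ends. In the phosphate list PHM8 stood at 1.48, PHO84 at 1.40, PHM6 at -1.24 and VTC1 at -0.59. In the nucleotide list URA10 stood at 1.87, PHM8 at 1.48, URA1, on chromosome XI, at -1.77 and URA2 at -1.24. Of 9 genes often used as strain markers 4 were higher and 4 lower (adjusted p = 0.862), with LEU2 at -1.65 and ADE2 at 0.67. With RPKM as deposited the counts of higher and lower genes were 26 and 7 for mating, 25 and 3 for meiosis, 18 and 5 for subtelomeric, 17 and 1 for phosphate, 7 and 3 for nucleotide and 7 and 1 for marker genes.

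The open reading frames YBR013C (chromosome II, 265492 to 265881) and YBR012C, which matched no RefSeq entry, had 0 reads in all 3 tSH2Δ libraries. In WT, YBR012C had 184 to 211 and YBR013C 232 to 267 reads per library. Against a floor set at the rescaled RPKM of 3 reads in a tSH2Δ library, they were at least 117-fold and at least 145-fold lower in rescaled RPKM in tSH2Δ, respectively. Reads alone do not show whether these loci are silent or missing from the mutant strain, whose DNA was not analysed here. They were the 2 genes with 0 reads in every tSH2Δ library and at least 3 in every WT library, and 0 genes had the reverse. The annotated neighbours of YBR013C, IPP1 and GRX7, were measured in both strains, with log2 fold changes of -1.53 and -0.66. YER053C-A, a short open reading frame on chromosome V (260933 to 261046), had a log2 fold change of 5.29 (SE 0.196), with 17.8 ± 5.62 rescaled RPKM in WT and 712.9 ± 5.14 in tSH2Δ (SD, n = 3).

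Genes on chromosome XI were lower in tSH2Δ as a block. A trend with abundance does not account for it, since the difference in median log2 fold change from the other chromosomes was -0.90 before and -0.767 after each gene was set against genes of the same level. Nor do a few regions account for it, since 12 of 12 windows of 25 genes had a median below 0, between -1.12 and -0.66, while the lowest of 212 windows elsewhere was at -0.44. Ribosomal protein genes on XI (5) minus those elsewhere (133) differed by -0.740 in mean log2 fold change (two-sided permutation test, p = 0.00102). A change acting on all gene classes predicts this, but these 5 are among the 313 genes that showed the pattern. The value is thus no independent support. The median level of XI genes stood 1.13 above that of all genes in WT, outside the range of the other 15 chromosomes (-0.65 to 0.11). In tSH2Δ it stood at 0.02, inside the range there (-0.41 to 0.11). A candidate explanation, as a hypothesis found on these data, is an extra copy of chromosome XI in the WT cells rather than an effect of the tSH2 deletion on its genes, which DNA signal over that chromosome in each strain, such as ATAC-seq, would test and which was not analysed here.

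Ribosomal protein and ribosome biogenesis genes were lower in tSH2Δ. Both lists together had a median log2 fold change of -0.951, below all of 10000 lists matched on level (lowest -0.80), and the biogenesis factors alone, at -0.924, lay below all of theirs (lowest -0.72) and kept their call after quantile normalization at the preset correlation (adjusted p = 0.48 with an estimated correlation under the main scaling), so the matched lists argue against the abundance trend as the whole cause for that list. For the ribosomal protein genes alone the trend stays open, since their median of -0.958 stood near the matched median of -0.80, at percentile 0.43, and quantile normalization left 67 of 138 lower and ended the call. The genes of chromosome XI do not account for the pattern, as the median without XI was -0.937. With RPKM as deposited 76.2% of members stayed lower and past the threshold, with list medians of -0.38 and -0.34. That setting applies another single factor per library, so it cannot exclude scaling as the reason for the calls. Relative to all genes the medians hardly moved, from -0.97 to -0.95 for ribosomal proteins and from -0.93 to -0.92 for biogenesis factors. A change in ribosome production in the mutant stays open. It may reflect the loss of the domain, slower growth, taken up in the next pattern, or another strain difference, as on chromosome XI.

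Environmental stress response genes were higher in tSH2Δ. The tSH2Δ replicate 3, in which HSP12 was highest, does not account for this, since 53 members were higher and past the threshold without it, and the median of 1.05 lay above all of 10000 lists matched on level, the highest at 0.43. A stress score, the median of this list minus that of the ribosome lists, differed between strains by 2.32 on the log2 scale, but it is built from the very lists that showed the pattern and so tests nothing about growth stage. Each strain had its own cultures, so growth stage or growth rate cannot be told apart from the deletion here. Nor can any other difference between the strains, such as the one on chromosome XI.

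Other lists against lists matched on level gave these values. Glycolysis and fermentation genes, at -1.28, lay below all matched lists (lowest -1.23), and oxidative phosphorylation genes, at 0.04, lay above all of theirs (median -0.50, highest -0.14). Heat shock factor targets, at -0.58, lay at percentile 89.0 of theirs, whose median was -0.77, and histone genes, at -0.53, at percentile 82.2, around -0.75. Amino acid biosynthesis genes, at -0.57, lay at percentile 0.57 of theirs, galactose and glucose-repressed genes, at 0.60, at percentile 99.4, subtelomeric families, at 0.77, at percentile 99.3, and cell wall integrity genes, at 0.04, at percentile 97.1. The subtelomeric value rests on the 26 of 76 members that passed the filter, and relative to all genes their median was 0.76, against 0.05 over 51 members with no filter, 0.44 with a pseudocount of 5 RPKM and 0.40 after quantile normalization. Without the listed genes and chromosome XI, the relation of log2 fold change to level kept a Spearman's rho of -0.42 over 5139 genes. The relation to gene length had a rho of -0.015.

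Whether chance could give as many calls was looked at by dividing the 6 libraries into 3 and 3 in each of the 10 ways. The real split gave 5267 genes by limma and the highest of the others gave 0, with 2 to 16 genes at an unadjusted p under 0.05, but 1 of 10 splits cannot give a share under 0.05.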
